A study of Mus musculus with 7 samples.

How the data were processed

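T cell receptor libraries were measured from sorted mouse T cells in 7 samples, of which 5 came from cGVHD recipients and 2 from No GVHD recipients. Per the labels' protocols, RNA was extracted with a miRNeasy micro kit and libraries were made with the SMARTer mouse TCR a/b profiling kit, which amplifies rearranged transcripts from the constant region through template switching. Each sample had a table for TRA and a table for TRB, 14 in all. Per the file headers, each table listed CDR3 clonotypes with a read count, the fraction of the table's reads, the CDR3 nucleotide and amino acid sequence with base qualities, and scored V, D, J and C segments. The deposited counts were whole reads with no molecular identifier, and the deposited fraction values equalled the count over the table's total. The genome build mm10 was named in the submitters' processing notes. The clonotype caller, its version and its filters, the pooling of animals and the number of sorted cells are not given in the sources used here. The lowest base quality in a listed CDR3 was 21.

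Reads per sample numbered 295295 to 420270 for TRB and 431160 to 799513 for TRA. A CDR3 without a frame shift or stop codon was taken as in frame. Reads out of frame or with a stop made up 3.05 to 12.1% of TRB and 6.33 to 15.8% of TRA reads. The first-listed, best-scoring V and J segments were used without allele. Copies of V alpha genes from the duplicated part of the locus (names with D or N, and the DV suffix) were merged into 1 gene, because 73.6 to 77.8% of TRA clonotypes had several V hits, against 3.58 to 4.46% for TRB. TRAV shares are therefore those of groups of near-identical copies. Of 79 V genes found after merging, 72 matched a mouse gene table of the assembly GRCm38.p6, which gave segment positions. A clonotype was defined by CDR3 nucleotide sequence, V and J, with at least 2 reads. Clonotypes of 1 read held 0.0481 to 1.72% of TRB and 0.0228 to 0.783% of TRA reads.

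Diversity was described by the share of the most abundant and of the 10 most abundant clonotypes, by clonality (1 minus Shannon entropy over the log of the number of clonotypes), by the number of clonotypes that made up 50% of reads and by the expected number of clonotypes at the smallest in-frame depth of the chain (exact hypergeometric rarefaction, 259464 reads for TRB and 396094 for TRA). Sharing was measured over all 21 pairs of libraries as the number of clonotypes and share of reads found in the other library, and by the Morisita-Horn index with 100 bootstrap draws of reads. The No GVHD Tfh libraries gave the background. Shares of single libraries have exact Clopper-Pearson 95% intervals, and 0 reads allow up to 3 reads of the total. On 20 simulated pairs of repertoires of 600 clonotypes with 200 shared, these measures were recovered with errors of at most 0.249 percentage points for shared reads, 0.000756 for the Morisita-Horn index and 0.451% for rarefied numbers. Reads there were independent draws, and rarefaction was checked at a lower depth than that used. This checks the calculation only and leaves out errors from PCR and from the number of sorted cells.

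V gene use was tested on in-frame read counts per V gene with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), with the in-frame reads of the chain as library size, edgeR's filter on low counts and Benjamini-Hochberg adjustment within a chain at a threshold of 0.05. CD69+ and CD69- Trh libraries were compared with tissue as a block, which left 1 residual degree of freedom, and the 5 cGVHD libraries were compared with the 2 Tfh libraries. No test was made between single libraries. In simulated data with the real means and dispersions, the test of 24 TRB genes between cGVHD and Tfh libraries recovered 31.5% of genes changed 4-fold and 94.5% of genes changed 16-fold. For 50 TRA genes it recovered 2.75% and 31.5%. For CD69 status it recovered 2.0% and 20.5% of 24 TRB genes and 2.0% and 3.25% of 46 TRA genes. In each of these simulations at most 1.10% of unchanged genes were called, but since few changed genes were recovered, unchanged genes made up a large part of some sets of calls. At 4-fold and 16-fold they were 66.7% and 12.8% of TRB calls and 27.3% and 23.5% of TRA calls for CD69 status, and 11.3% and 5.50% of TRB calls and 26.7% and 6.67% of TRA calls between cGVHD and Tfh libraries.

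Groups, designs, alternatives and gene lists were fixed before the data were examined, apart from the added alternatives named in the closing section. The lists were V beta families that BALB/c mice delete through endogenous superantigens, V beta families they keep, V beta families favoured by iNKT cells, and the invariant alpha chains of iNKT and MAIT cells. Named clonotypes were the 3 most abundant of each library and chain, and the 10 TRB and 5 TRA clonotypes with the highest mean share among those found in all 5 cGVHD libraries. Those leading the Tfh libraries are named with the other observations. Named V genes were all list members, every gene past a test, and, for the liver and lung CD69 comparisons and blood against the mean of 4 Trh libraries, the 5 genes per chain and direction with the largest fold among those at 1% of reads or more on a side and changed at least 2-fold. Genes and clonotypes outside this rule are given as the largest clonotype of a named V gene or are said to be chosen after their values were seen. TRBV31, a member of the kept list, was not among the V genes found.

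Alternatives covered the clonotype definition (amino acid or nucleotide CDR3 alone), the read minimum (1 or 10 reads), clonotypes out of frame, merging of clonotypes 1 mismatch from a clonotype with at least 20 times the reads, thinning to equal depth, the 200 most abundant clonotypes, a minimum of 1% of the more abundant side for sharing, weighting of V genes by distinct clonotypes, removal of the 5 most abundant clonotypes, TMM factors, DESeq2 size factors, DESeq2's Wald test, no filter, no tissue term and removal of each library. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.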

Results

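The data set held T cell receptor libraries from a mouse model of chronic graft-versus-host disease (cGVHD), in which donor T cells attack the tissues of a marrow recipient. Irradiated BALB/c mice had been given C57BL/6 marrow depleted of T cells, either alone (No GVHD) or with donor Thy1.2+ cells (cGVHD). From cGVHD recipients, peripheral T helper (Tph) cells, which carry high PD-1 and lack the follicle-homing receptor CXCR5, were sorted from blood. Tissue-resident T helper (Trh) cells with low PSGL-1 and high PD-1 were sorted from liver and lung and divided by CD69, a marker of retention in tissue. Splenic follicular helper (Tfh) cells of the No GVHD mice served as the comparison. The 5 cGVHD populations had 1 library each and the Tfh cells had 2, so 7 libraries were measured for the receptor alpha chain (TRA) and beta chain (TRB).

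In-frame reads numbered 329573 (blood Tph), 399665 (liver CD69+ Trh), 290423 (liver CD69- Trh), 291947 (lung CD69+ Trh), 259464 (lung CD69- Trh), 376375 (Tfh 1) and 285214 (Tfh 2) for TRB. For TRA they numbered 403732, 446563, 396094, 415812, 419997, 712551 and 525962 in that order. A clonotype was a CDR3 nucleotide sequence with its V and J segments, in frame and with at least 2 reads. Shares of reads in single libraries carry exact (Clopper-Pearson) 95% binomial intervals. These intervals, and the limits given for 0 reads, cover counting error only, because PCR reads without molecular identifiers are not independent molecules. No difference between single cGVHD libraries has a replicate check, and the labels do not say which animals gave which library. The p-values therefore measure only the spread between these samples, partly pooled over V genes, and treat libraries that may share animals as independent. Each SD given for the 2 Tfh libraries is likewise a spread between libraries that may not be independent.

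The title of the series asks whether circulating Tph cells belong to the same pool as the Trh cells of the target tissues, which the overlap of clonotypes addresses. Clonotypes found in at least 1 Trh library made up 58.3% of the TRB reads of blood Tph cells (interval 58.1 to 58.5%), carried by 240 of 651 clonotypes. The background, measured the same way against either No GVHD Tfh library, was 0.348% of reads (interval 0.328 to 0.368%) and 7 clonotypes, although the Tfh libraries held many more clonotypes. The Tfh cells came from other mice, which were given no donor Thy1.2+ cells. Liver CD69- Trh cells held 45.6% of the blood TRB reads, lung CD69+ Trh cells 43.2%, lung CD69- Trh cells 33.2% and liver CD69+ Trh cells 26.2%. In the other direction, blood Tph clonotypes covered 52.6% of the reads of liver CD69- Trh cells and 29.9 to 36.8% of the reads of the other 3 Trh libraries. The alpha chain gave 52.5% for blood Tph reads found in Trh cells (interval 52.4 to 52.7%) and a higher background of 10.4% in the Tfh libraries (interval 10.3 to 10.5%).

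The separation from the background held for TRB under each definition of a clonotype tried and was lost for TRA at the level of the protein sequence. When clonotypes were matched by CDR3 amino acid sequence alone, the Trh libraries held 59.1% and the Tfh libraries 9.73% of the blood TRB reads. For TRA the corresponding shares were 57.04% and 53.7%.

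**Figure D1:**
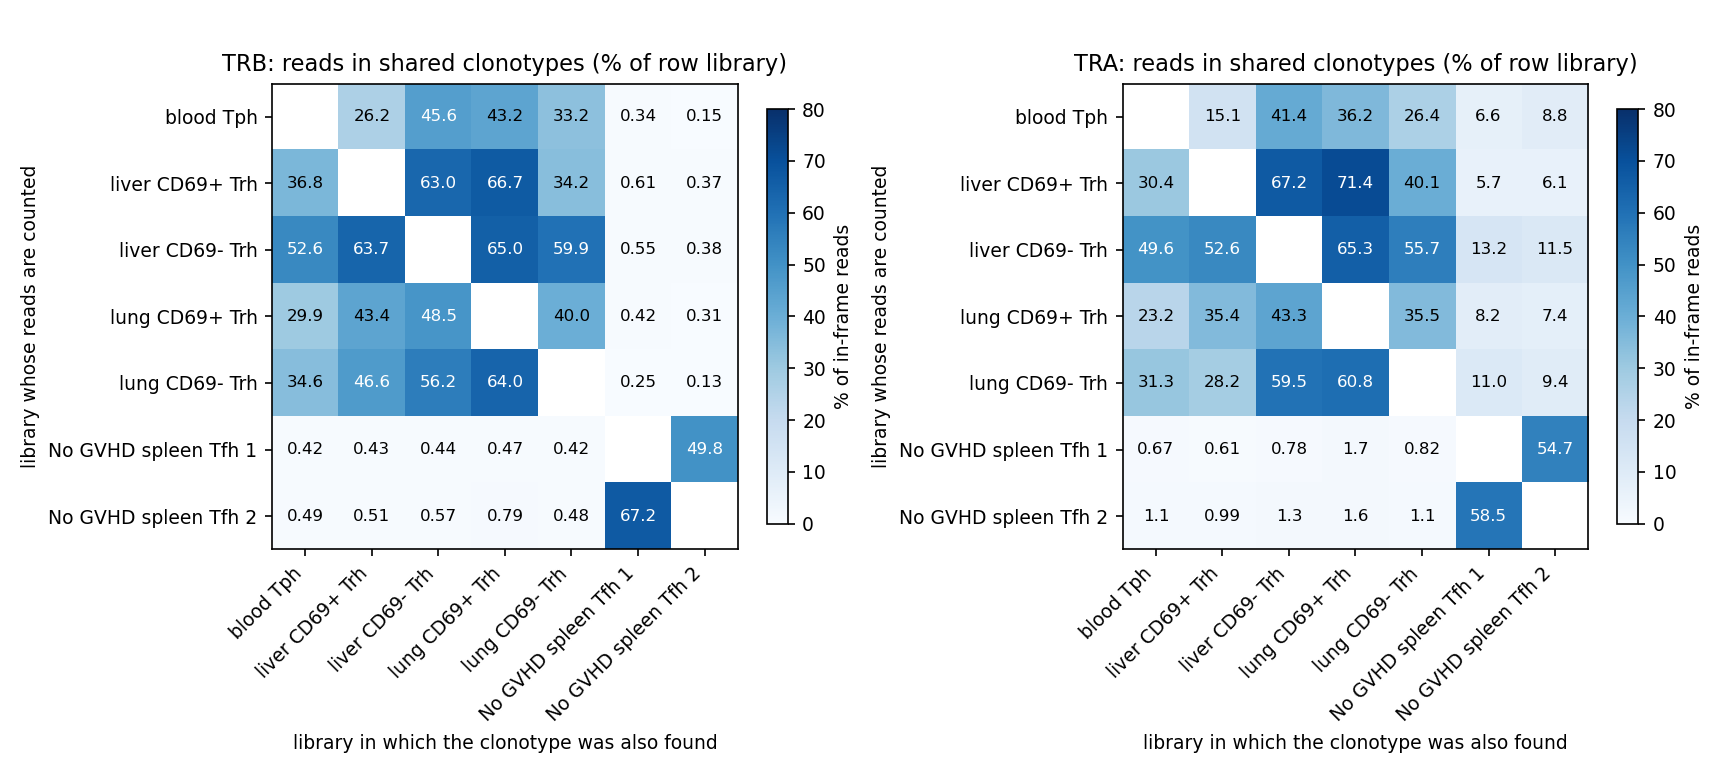
Percent of the in-frame TRB and TRA reads of each library that fell in clonotypes also found in each other library. For TRB, blood Tph reads fell in clonotypes of single Trh libraries for 26.2 to 45.6% and in clonotypes of single Tfh libraries for 0.338% and 0.149%.

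A core of clonotypes ran through all 5 cGVHD populations. The cGVHD libraries together held 3106 TRB clonotypes, of which 627 (20.2%) were found in at least 2 libraries and 40 in all 5. Being found needed only 2 reads, so some of the 40 were present in a library by traces. In liver CD69+ cells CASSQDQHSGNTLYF had 3 reads and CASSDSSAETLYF 5. The 40 were not counted again with a higher minimum. Those 40 took 17.5% of the reads in blood, 24.1% in liver CD69+, 37.0% in liver CD69-, 18.1% in lung CD69+ and 19.4% in lung CD69- cells, and 3 of the 40 were seen in a Tfh library. For TRA, 15 of 2361 clonotypes were in all 5 libraries and took 9.06 to 27.9% of reads, and 2 of the 15 were seen in a Tfh library.

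The most abundant of these shared receptors was the TRB clonotype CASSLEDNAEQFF, a joining of TRBV3 to TRBJ2-1 with the CDR3 sequence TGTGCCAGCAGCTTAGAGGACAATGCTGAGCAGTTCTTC. It ranked first in 3 libraries, with 9.39% of reads in liver CD69+ cells (interval 9.30 to 9.48%), 15.2% in liver CD69- cells (15.0 to 15.3%) and 4.37% in lung CD69+ cells (4.30 to 4.45%). It took 1.93% in lung CD69- cells and 0.713% in blood (0.685 to 0.743%), and had 0 reads in both Tfh libraries, which allows shares of up to 0.000797% and 0.00105%. The leading TRA clonotype was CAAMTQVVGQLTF, a joining of TRAV14-3 to TRAJ5 with the CDR3 sequence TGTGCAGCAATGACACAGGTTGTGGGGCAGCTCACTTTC. It took 15.6%, 19.0%, 5.54%, 1.59% and 0.605% in the same order of libraries and was also unseen in the Tfh cells. In the mouse genome (GRCm38.p6, the assembly family of mm10), the TRBV3 segment lies on chromosome 6 from 41048394 to 41048824 and the TRAV14-3 segment on chromosome 14 from 53763196 to 53763694. TRAV14-3 here stands for a group of merged copies, so the copy used by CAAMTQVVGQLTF, and its position, are not known.

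Blood Tph cells had their own order of leading receptors, and most of them recurred in tissue. The first in blood was the TRBV5 clonotype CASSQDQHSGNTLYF with 3.28% of TRB reads. It had 1.26% in lung CD69- cells and 0.855% in liver CD69- cells, but 0.0168% in lung CD69+ cells and 3 reads (0.000751%) in liver CD69+ cells. The second, the TRBV5 clonotype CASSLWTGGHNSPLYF, took 2.42% in blood, 1.47% in liver CD69-, 1.42% in lung CD69-, 0.634% in lung CD69+ and 0.228% in liver CD69+ cells. The third, the TRBV5 clonotype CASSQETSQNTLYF, took 2.01% in blood, 0.588% and 0.707% in the liver CD69+ and CD69- cells and 0.0555% in lung CD69+ cells, with 0 reads in lung CD69- cells (limit 0.00116%). Among TRA chains, the TRAV10 clonotype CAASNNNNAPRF led in blood with 3.36% and took 2.79% in lung CD69- cells, against 0.393% or less in the other Trh libraries. The TRAV6-5 clonotype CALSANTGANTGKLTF took 2.57% in blood and 1.05% in liver CD69- cells, with 0 reads in liver CD69+ cells. The TRAV8-1 clonotype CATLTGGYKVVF took 2.38% in blood and had 0 reads in each Trh library (limits 0.000672 to 0.000757%).

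Several leading tissue receptors were missing from blood at this depth. The TRBV13-1 clonotype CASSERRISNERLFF took 6.85% of lung CD69- reads and 0.516% in lung CD69+ cells, with 0 reads in blood (limit 0.000910%) and in liver CD69- cells and 6 reads in liver CD69+ cells. The TRBV5 clonotype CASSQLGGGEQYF took 3.86% in liver CD69+ cells and 0.308% in liver CD69- cells, and the TRBV14 clonotype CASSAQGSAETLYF took 2.92% in lung CD69+ and 1.67% in liver CD69+ cells, both with 0 reads in blood. The TRBV2 clonotype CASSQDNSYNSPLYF took 2.04% in lung CD69- cells and was otherwise seen with 2 reads in liver CD69+ cells. Other receptors were present in blood and had a higher share in some or all of the Trh libraries. The TRBV1 clonotype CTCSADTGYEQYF took 2.72% in liver CD69+, 1.34% in liver CD69-, 2.04% in lung CD69+, 1.01% in lung CD69- and 0.0886% in blood. The TRBV13-3 clonotypes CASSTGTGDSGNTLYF and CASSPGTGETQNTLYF took 3.48% and 2.03% in liver CD69- cells against 0.0646% and 0.282% in blood, and the second had 0.0858% in liver CD69+ cells. The TRBV29 clonotype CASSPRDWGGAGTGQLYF took 3.02% in liver CD69+ cells and 0.691% in blood, but 0.209%, 0.176% and 0.0193% in liver CD69-, lung CD69+ and lung CD69- cells. The TRBV29 clonotype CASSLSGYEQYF took 2.56% in lung CD69- cells, 1.32% in liver CD69- cells and 0.798% in blood, but 0.493% and 0.427% in liver CD69+ and lung CD69+ cells. The TRBV30 clonotype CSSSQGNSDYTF took 2.06% in lung CD69+ cells and 0.770% in blood, but 0.163% in liver CD69- cells, 0.0108% in lung CD69- cells and 0 reads in liver CD69+ cells. The TRBV13-1 clonotype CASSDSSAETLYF took 1.83% in liver CD69- and 1.44% in lung CD69- cells against 0.226% in blood, 0.151% in lung CD69+ cells and 5 reads in liver CD69+ cells. In contrast, the TRBV13-2 clonotype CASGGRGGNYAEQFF was highest in blood at 1.81%, with 0.804% or less in the Trh libraries.

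The remaining leading TRA receptors fell into the same kinds. In liver CD69+ cells, the TRAV10 clonotype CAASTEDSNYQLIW took 7.26% and the TRAV7-5 clonotype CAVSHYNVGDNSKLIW 3.92%, both with 0 reads in blood. The TRAV7-5 clonotype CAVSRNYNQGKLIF took 4.23% and the TRAV16 clonotype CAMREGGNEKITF 2.15% in lung CD69+ cells, also with 0 reads in blood. Lung CD69- cells were led by the TRAV16 clonotype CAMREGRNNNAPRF (3.23%, with 1.40% in blood) and the TRAV6-7 clonotype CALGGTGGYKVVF (3.07%, with 0 reads in blood). The TRAV21 clonotype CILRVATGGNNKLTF took 2.72% in liver CD69- and 1.96% in lung CD69- cells, 0 reads in blood, and 49 and 35 reads in the Tfh libraries. The TRAV7-4 clonotype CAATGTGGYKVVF (0.182 to 1.21%) and the TRAV4-4 clonotype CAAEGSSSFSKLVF (0.0741 to 1.59%) were found in all 5 cGVHD libraries. The TRAV4-4 clonotype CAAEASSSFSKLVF was the only named receptor that was abundant in all 7 libraries, with 1.54 to 4.89% in cGVHD cells and 0.458% and 0.801% in the Tfh cells.

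**Figure D2:**
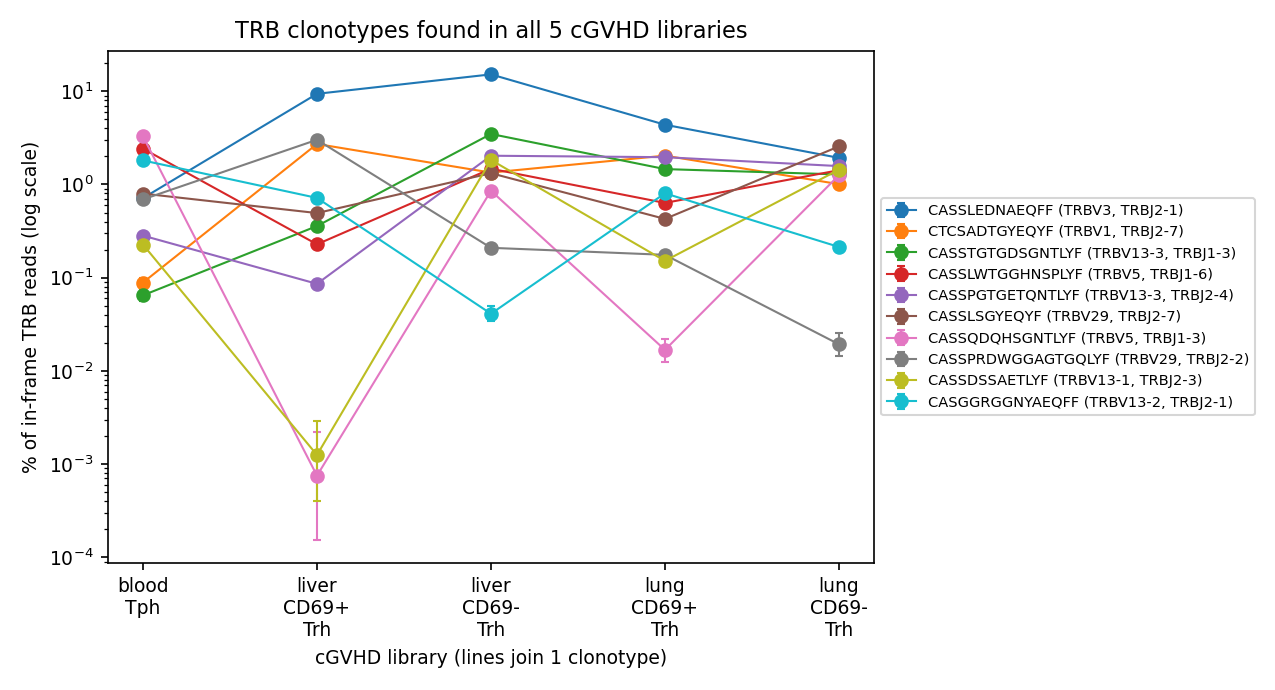
Percent of in-frame TRB reads (log scale, exact 95% intervals) in the 5 cGVHD libraries for the 10 TRB clonotypes with the highest mean share among those found in all 5. The TRBV3 clonotype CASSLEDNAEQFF ran from 0.713% in blood to 15.2% in liver CD69- cells.

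Similarity of whole repertoires was summarised with the Morisita-Horn index, which is 0 for no overlap and 1 for identical shares. For TRB the liver CD69+ and CD69- Trh cells were the most alike (0.713), followed by liver CD69+ with lung CD69+ cells (0.534), liver CD69- with lung CD69+ cells (0.4996) and lung CD69+ with lung CD69- cells (0.338). Blood Tph cells had indices of 0.125 to 0.189 with the 4 Trh libraries, and no cGVHD library exceeded 0.00133 with a Tfh library. The 2 Tfh libraries had an index of 0.253 with each other and shared 3337 TRB clonotypes, which took 49.8% and 67.2% of their reads. For TRA the liver pair was again the highest (0.809), the lung pair had 0.290, and blood Tph cells were closest to lung CD69- Trh cells (0.323) and farthest from liver CD69+ Trh cells (0.0744). A large part of the liver similarity came from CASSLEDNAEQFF alone. Without it, an alternative chosen after the data were seen, the index of the TRB liver pair was 0.312, that of the lung pair 0.284, that of liver CD69- with lung CD69+ cells 0.413 and the mean of blood Tph with the 4 Trh libraries 0.173 instead of 0.160. The liver pair was then no longer the most alike, and blood Tph cells were closest to liver CD69- Trh cells (0.255 instead of 0.154). Without the leading TRA clonotype the TRA liver pair had 0.300, below liver CD69- with lung CD69- cells (0.449), blood Tph with lung CD69- cells (0.317) and liver CD69- with lung CD69+ cells (0.313), and blood Tph with liver CD69- cells had 0.252 instead of 0.120.

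By reads, the cGVHD libraries held few, large clonotypes and the Tfh libraries many small ones. At a matched depth of 259464 reads, the expected number of TRB clonotypes was 650.0 in blood Tph cells, 581 in liver CD69+, 885 in liver CD69-, 1543 in lung CD69+ and 489 in lung CD69- Trh cells, against 14888 ± 4260 (SD, n = 2) in Tfh cells. The Tfh mean was 22.9 times the median of the cGVHD libraries, or 9.91 times when clonotypes needed 10 reads. The 10 most abundant clonotypes took 18.9% of TRB reads in blood (interval 18.8 to 19.0%), 30.3% in liver CD69+ (30.2 to 30.5%), 32.0% in liver CD69- (31.9 to 32.2%), 19.7% in lung CD69+ (19.6 to 19.9%) and 23.4% in lung CD69- cells (23.2 to 23.5%), against 8.502 ± 1.08% in Tfh cells. It took 31 to 99 clonotypes to reach 50% of reads in the cGVHD libraries and 614.5 ± 233 in Tfh cells. The alpha chain gave the same ordering of clonotype number: at 396094 reads there were 447, 354, 673, 1305 and 291 clonotypes in blood, liver CD69+, liver CD69-, lung CD69+ and lung CD69- cells and 17806 ± 1297 in Tfh cells. The 10 most abundant TRA clonotypes took 21.2%, 42.3%, 35.2%, 21.1% and 23.4% in that order, against 7.07 ± 0.684% in Tfh cells. Here the highest cGVHD share was in liver CD69+ cells, while for TRB it was in liver CD69- cells.

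Clonality, which corrects the evenness of a repertoire for its number of clonotypes, separated the groups less. For TRB it was 0.161 in blood, 0.202 and 0.248 in liver CD69+ and CD69- cells, 0.166 and 0.173 in lung CD69+ and CD69- cells and 0.153 ± 0.0107 (SD, n = 2) in Tfh cells. For TRA it was 0.239 and 0.254 in the liver libraries, 0.140 to 0.160 in the other cGVHD libraries and 0.141 ± 0.00291 in Tfh cells. The number of sorted cells is not given in the sources used here, so the difference in clonotype number includes any difference in cell input. They also include any effect of the donor Thy1.2+ cells, which only the cGVHD recipients were given.

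**Figure D3:**
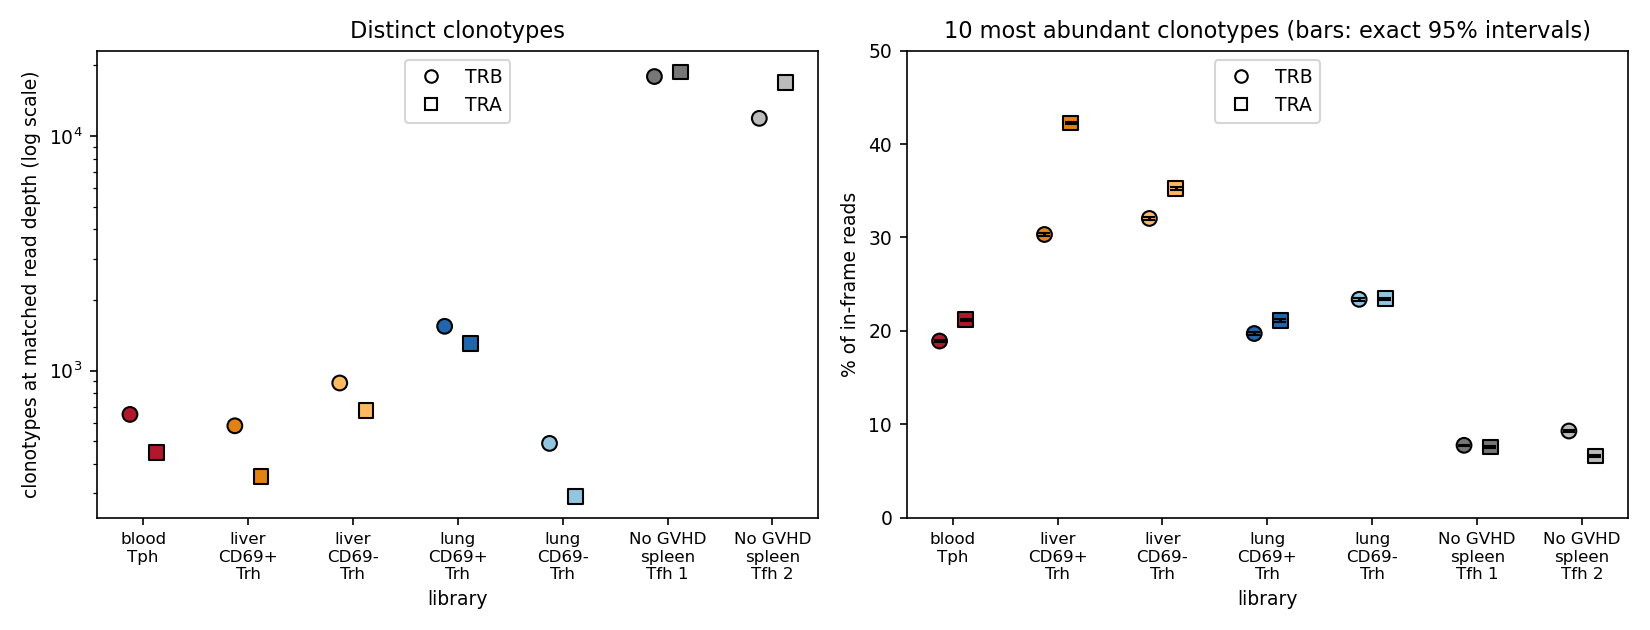
Expected number of clonotypes at matched read depth (log scale) and share of reads in the 10 most abundant clonotypes for each library, circles for TRB and squares for TRA, with exact 95% intervals on the shares. All cGVHD libraries lay below both Tfh libraries in clonotype number and above them in the share of the 10 most abundant.

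CD69 status within a tissue addresses how cells with the retention marker differ from those without it. In both liver and lung, 4 TRA and 3 TRB genes differed at least 2-fold by reads, with 1% of reads or more on a side. TRAV21, TRAV8-1, TRAV7-5, TRBV4 and TRBV12-2 went in the same direction in both tissues, and TRAV7-6 and TRBV30 in opposite directions. The tissues shared clonotypes, so agreement between them is not independent. By distinct clonotypes, TRAV21 and TRAV8-1 were lower in CD69+ cells of both tissues, while TRBV4 was not higher in either tissue and TRAV7-5 and TRBV12-2 were higher in 1 tissue only. TRAV21 took 0.452% of reads in liver CD69+ against 6.84% in liver CD69- cells and 1.28% in lung CD69+ against 6.06% in lung CD69- cells. TRBV4 had a higher share of reads in CD69+ cells, at 4.602% against 1.91% in liver and 6.65% against 2.71% in lung, but not of clonotypes (4.10% against 4.52% and 4.47% against 4.50%). The TRAV21 reads of liver CD69- cells were spread over 14 clonotypes, of which the largest, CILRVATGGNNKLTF, made up 39.8%.

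By edgeR's quasi-likelihood test with tissue as a block and Benjamini-Hochberg adjustment, 3 of 46 TRA genes passed at an adjusted p of 0.05. TRAV21 was lower in CD69+ cells (log2 fold change -3.08, SE 0.41, adjusted p = 2.95e-05), as was TRAV8-1 (log2 -1.14, SE 0.33, adjusted p = 0.0417), and TRAV2 was higher (log2 2.32, SE 0.55, adjusted p = 0.0124). With 1 residual degree of freedom, these p-values and SEs draw largely on the spread that edgeR pools over V genes. They do not show that a change was replicated. By reads, TRAV21 was 15.1-fold lower in CD69+ cells of liver and 4.72-fold lower in those of lung. None of the 3 passed with DESeq2's Wald test or without the tissue term, with log2 fold changes close to those above (TRAV21 -3.08 and -2.89, TRAV2 2.32 and 2.48, TRAV8-1 -1.14 and -1.13). With distinct clonotypes none passed either, at log2 -0.94 for TRAV21 and -0.998 for TRAV8-1, with TRAV2 below the filter. TRAV8-1 also missed the threshold with TMM factors (log2 -1.08, adjusted p = 0.234), and TRAV2 and TRAV8-1 with DESeq2 size factors. The TRAV2 reads of liver CD69+ cells were 99.9% a single clonotype, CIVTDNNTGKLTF. Of 24 TRB genes, 0 passed with edgeR, with 0 at an unadjusted p under 0.05, and 0 passed with DESeq2, with 2 at an unadjusted p under 0.05. In simulated data the TRB test recovered 20.5% and the TRA test 3.25% of genes changed 16-fold, so differences of this size could go unseen, and 23.5% of the TRA calls there were of unchanged genes.

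Within liver, 9 TRB genes differed at least 2-fold between CD69+ and CD69- cells with 1% of reads or more on a side. TRBV12-2 (1.14% against 0.119%), TRBV26 (4.12% against 1.10%) and TRBV29 (8.78% against 4.06%) were higher in CD69+ cells. TRBV20 (0.514% against 4.64%), TRBV13-3 (3.83% against 13.0%), TRBV22 (0.530% against 1.84%) and TRBV15 (0.426% against 1.25%) were lower. TRBV30 had 0 reads in liver CD69+ cells and 1.28% in liver CD69- cells, at least 1700-fold lower against the limit of 3 reads. That bound counts reads and not cells. The liver CD69- reads came from 4 clonotypes, with 70.7% in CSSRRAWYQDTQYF, so the absence rests on few receptors. Among alpha chains, TRAV2 (3.73% against 0.602%), TRAV7-5 (10.1% against 4.26%) and TRAV7-6 (2.49% against 1.08%) were higher, and TRAV13-4 (0.159% against 1.16%), TRAV11 (0.165% against 1.05%), TRAV12-3 (0.773% against 2.16%) and TRAV8-1 (1.48% against 3.34%) were lower. By distinct clonotypes, TRBV30 and TRAV13-4 still differed at least 2-fold, but each had only 4 clonotypes in liver CD69- cells. TRBV4, TRBV12-2, TRBV29, TRAV7-6, TRAV12-3 and TRAV6-5 ran the other way.

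Within lung, 8 TRB and 16 TRA genes met the same size rule. TRBV12-1 (1.17% against 0.100%), TRBV30 (2.12% against 0.222%), TRBV3 (8.78% against 2.75%) and TRBV14 (6.69% against 2.45%) were higher in CD69+ cells, and TRBV2 (2.79% against 6.10%) and TRBV13-1 (8.09% against 17.5%) were lower. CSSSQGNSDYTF made up 97.3% of the TRBV30 reads of lung CD69+ cells, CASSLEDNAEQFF 49.8% of the TRBV3 reads there, and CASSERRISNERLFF 39.1% of the TRBV13-1 reads of lung CD69- cells. Among the 16 TRA genes, the largest differences were TRAV19 (1.29% against 0.156%), TRAV9-1 (1.93% against 0.241%), TRAV17 (1.96% against 0.298%), TRAV5-4 (1.89% against 0.318%) and TRAV4-1 (1.11% against 0.395%) upward. TRAV9-3 (0.177% against 1.12%), TRAV8-2 (0.238% against 1.49%), TRAV9-2 (0.372% against 1.68%) and TRAV13-1 (0.854% against 2.13%) were lower in CD69+ cells. By distinct clonotypes, TRAV8-1, TRAV8-2 and TRAV12-2 still differed at least 2-fold, and TRBV30 (0.130% against 0.613%), TRBV4, TRAV7-5, TRAV4-1, TRAV9-2 and TRAV13-1 ran the other way. Some of these shares rest on few clonotypes, such as 3 of TRAV8-2 in lung CD69- cells and 2 of TRBV30 in lung CD69+ cells.

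Blood Tph cells differed from the mean of the 4 Trh libraries in 5 TRB and 13 TRA genes by the same rule. TRBV20 (6.09% against 2.14%) and TRBV12-1 (1.36% against 0.527%) were higher in blood, and TRBV3 (3.79% against 9.98%), TRBV4 (1.57% against 3.97%) and TRBV15 (0.805% against 1.81%) were lower. Among alpha chains, TRAV6-3 (1.38% against 0.157%), TRAV19 (3.96% against 0.625%), TRAV9-4 (2.46% against 0.403%), TRAV12-1 (1.58% against 0.279%) and TRAV7-6 (6.27% against 2.12%) were the 5 largest of 9 higher in blood. TRAV2 (0.0562% against 1.38%), TRAV6-6 (0.820% against 2.496%), TRAV14-3 (4.91% against 14.7%) and TRAV4-4 (4.35% against 9.60%) were lower. These are values of single libraries, with no test. Single Trh libraries moved some means by over 1.5 times: without liver CD69+ cells the TRAV2 mean was 0.599%, without liver CD69- cells the TRBV20 mean 1.31%, without lung CD69+ cells the TRBV12-1 mean 0.312%, the TRAV19 mean 0.402% and the TRAV9-1 mean 0.501% (0.859% with it), and without lung CD69- cells the TRAV6-3 mean 0.0844%. The difference fell under 2-fold for TRBV4 without lung CD69+ cells (1.96), for TRBV15 and TRAV3-3 without lung CD69- cells (1.66 and 1.96) and for TRAV6-5 without liver CD69+ cells (1.99). By distinct clonotypes, only TRAV19 (2.01% against 0.865%) and TRAV12-1 (1.57% against 0.553%) differed at least 2-fold, with 9 and 7 clonotypes in blood. TRAV2 (0.447% against 0.588%) and TRAV6-3 (1.12% against 0.956%) were close, and TRAV4-4 (6.26% against 5.48%) and TRAV6-5 ran the other way.

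The comparison of cGVHD libraries with No GVHD Tfh libraries sets disease, tissue and cell type apart from the control all at once, and these cannot be separated here. TRBV26 was the V gene that stood out, with 3.25%, 4.12%, 1.10%, 4.69% and 3.34% of reads in blood, liver CD69+, liver CD69-, lung CD69+ and lung CD69- cells, against 0.316 ± 0.105% (SD, n = 2) in Tfh cells. It was the only one of 24 TRB genes to pass edgeR's test (log2 fold change 3.39, SE 0.71, adjusted p = 0.0264, higher in 5 of 5 cGVHD libraries). The 5 libraries are not independent replicates. Clonotypes of another cGVHD library made up 58.3 to 83.0% of the TRB reads of each, and they may share animals. The same holds for the 2 Tfh libraries, whose 3337 shared TRB clonotypes took 49.8% and 67.2% of their reads. The difference did not rest on a few receptors, since TRBV26 made up 5.65 to 11.4% of distinct clonotypes in cGVHD libraries against 0.701% and 0.546% in Tfh libraries. Its segment lies on chromosome 6 from 41227525 to 41227913.

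The call was lost when blood, lung CD69+ cells or either Tfh library was left out (adjusted p = 0.0549, 0.0714, 0.0971 and 0.422), with log2 fold changes of 3.08 to 3.77. DESeq2 called 4 TRB genes, TRBV26, TRBV1 and TRBV3 as higher and TRBV21 as lower in cGVHD libraries. With distinct clonotypes in place of reads, 15 of 21 TRB genes passed, 8 higher and 7 lower. A clonotype found in several cGVHD libraries was counted in each of them. For TRA, 0 of 50 genes passed with edgeR, with 1 at an unadjusted p under 0.05. DESeq2 called 2 TRA genes, TRAV4-1 as higher and TRAV3-1 as lower, named here after their values were seen, and 8 of 29 genes passed with distinct clonotypes.

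TRBV26 belongs to a list, fixed in advance, of V beta families that BALB/c mice delete through endogenous superantigens and C57BL/6 mice keep. The 5 members together took 11.9% of reads in blood, 11.4% and 8.65% in liver CD69+ and CD69- cells and 18.9% and 16.4% in lung CD69+ and CD69- cells, against 8.56 ± 1.62% in Tfh cells. By distinct clonotypes the shares were 20.6 to 29.2% in cGVHD libraries against 11.7 ± 0.264% in Tfh cells. TRBV26 was the 1 member past the threshold, both over all TRB genes and adjusted over the list alone. TRBV16 took 5.16 to 9.39% of reads in cGVHD libraries against 5.05 ± 0.988% in Tfh cells, TRBV15 0.426 to 3.24% against 1.62 ± 0.0344%, TRBV12-1 0.100 to 1.36% against 1.01 ± 0.212% and TRBV12-2 0.119 to 1.28% against 0.565 ± 0.277%. With distinct clonotypes, TRBV26, TRBV16, TRBV15 and TRBV12-2 passed as higher and TRBV12-1 as lower in cGVHD libraries.

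The list of V beta families that BALB/c mice keep took 49.96 to 59.8% of reads in cGVHD libraries and 65.1 ± 5.65% in Tfh cells. Of its 8 measured members, 0 passed edgeR's test over all TRB genes and 0 adjusted over the list alone, while with distinct clonotypes TRBV13-1, TRBV13-3 and TRBV29 passed as lower and TRBV1 as higher in cGVHD libraries. TRBV13-1 took 6.05 to 17.5% in cGVHD libraries against 14.5 ± 0.0284% in Tfh cells, TRBV13-2 7.33 to 11.1% against 11.8 ± 0.221%, TRBV13-3 3.83 to 13.0% against 8.42 ± 0.275% and TRBV19 4.11 to 9.06% against 7.62 ± 2.999%. TRBV2 took 1.76 to 6.10% against 4.63 ± 0.935%, TRBV4 1.57 to 6.65% against 5.97 ± 0.757% and TRBV29 2.32 to 8.78% against 7.58 ± 0.963%. Of the 3 families that favour the invariant receptor of natural killer T (iNKT) cells, TRBV13-2, TRBV29 and TRBV1, 0 passed over all TRB genes and 1, TRBV1, passed adjusted over the list alone (adjusted p = 0.0292). TRBV1 took 7.02 to 10.9% of reads in cGVHD libraries against 4.57 ± 0.475% in Tfh cells, higher in 5 of 5. Together the 3 families took 18.4 to 29.6% in cGVHD libraries and 23.9 ± 0.710% in Tfh cells. Between CD69+ and CD69- Trh cells, 0 members of each of these 3 lists passed edgeR's test, over all TRB genes or adjusted over the list alone, and none of the 24 genes reached an unadjusted p under 0.05.

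**Figure D4:**
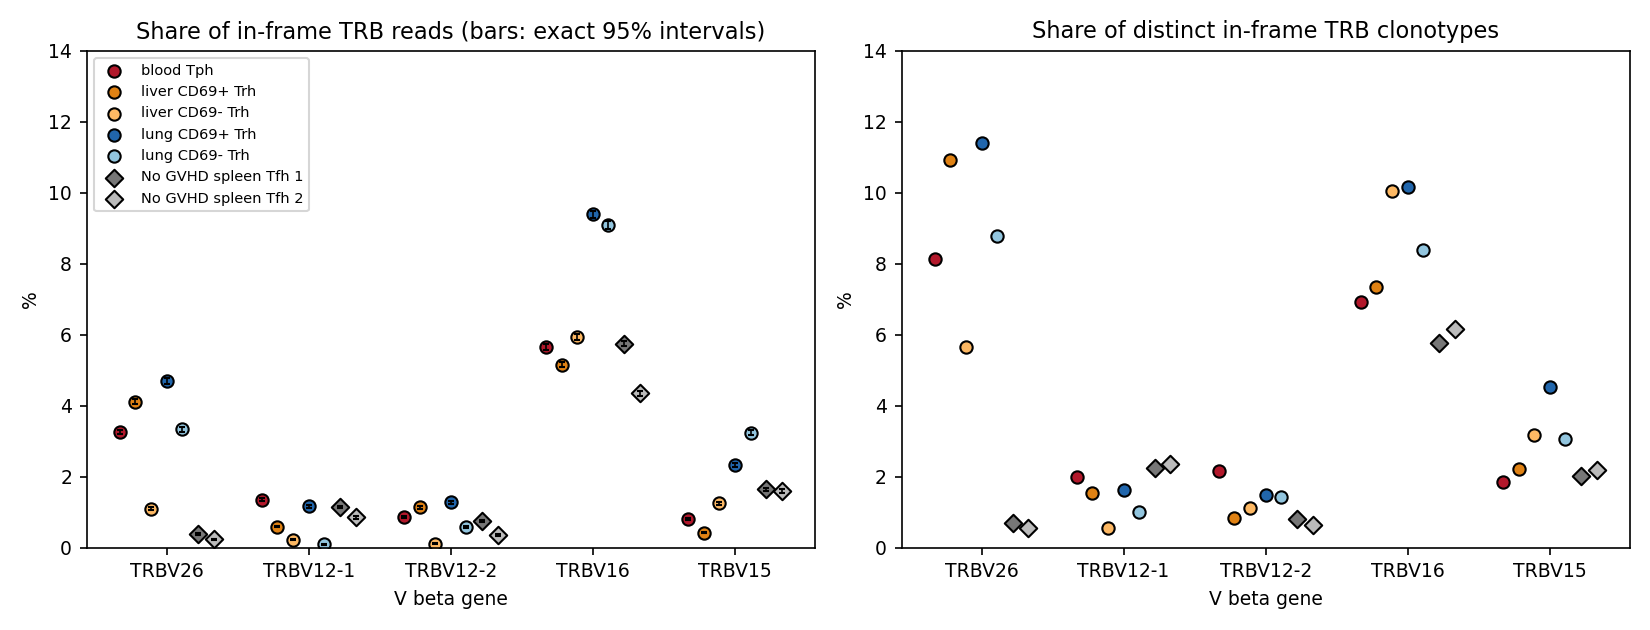
Percent of in-frame TRB reads (with exact 95% intervals) and of distinct TRB clonotypes in each library that used each of the 5 V beta families deleted by superantigens in BALB/c mice. TRBV26 took 5.65 to 11.4% of clonotypes in cGVHD libraries and 0.701% and 0.546% in Tfh libraries.

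Invariant alpha chains, which mark other T cell types that the gates could hold, were rare in all libraries. TRAV11 joined to TRAJ18, the chain of iNKT cells, took 0.608% and 0.315% of TRA reads in the 2 Tfh libraries (mean 0.462 ± 0.207%), with 13 clonotypes in each, and its canonical CDR3 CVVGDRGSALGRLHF took 0.404 ± 0.247%. The canonical CDR3 had 0 reads in all 5 cGVHD libraries. A single related chain, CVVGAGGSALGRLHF, was found in lung CD69+ Trh cells with 248 reads (0.0596%). TRAV1 joined to TRAJ33, the chain of mucosal-associated invariant T (MAIT) cells, had 0 reads in the cGVHD libraries and 51 and 3 reads in the Tfh libraries. These counts do not separate the groups: at the Tfh shares of distinct clonotypes (0.0720% and 0.0107%), the 5 cGVHD libraries would hold 2.21 TRAV11 to TRAJ18 clonotypes and 0.330 TRAV1 to TRAJ33 clonotypes, and 1 and 0 were found. The TRAV11 reads of liver CD69- Trh cells held no TRAJ18 chain, and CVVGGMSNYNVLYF made up 80.2% of them.

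Beta chain CDR3 regions appeared longer in cGVHD libraries, and TRBV26 accounted for most of the difference. Weighted by reads, the mean TRB length was 14.2 to 14.8 residues in cGVHD libraries against 13.9 ± 0.184 (SD, n = 2) in Tfh cells, a difference of 0.822 residues between the cGVHD median and the Tfh mean. Without TRBV26 the difference was 0.171 residues. The deposited CDR3 of 576 of 579 TRBV26 clonotypes began with SNSP, upstream of the conserved cysteine, and 577 of them were longer than 20 residues. Mean TRA length was 13.5 to 13.6 residues in cGVHD libraries and 13.5 ± 0.0895 in Tfh cells.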

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

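All tests in this part except that of inserted nucleotides were chosen after the result was seen.

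The TRB clonotypes shared between cGVHD libraries, which answer whether blood Tph and tissue Trh cells draw on the same receptors, were weighed only against carry-over of reads and repeated rearrangement. Other explanations, including any from the preparation of the tissue samples, were not weighed. Carry-over of reads would leave traces of every abundant clonotype everywhere, yet at least 34 of the 100 most abundant TRB clonotypes of a library (median 48.5 over 20 ordered pairs) had 0 reads in another cGVHD library. Such absences speak against carry-over as the source of most shared reads, not of clonotypes seen by few reads. Of 1-read TRB clonotypes, 0.781 to 23.0% had 100 or more reads in a single other cGVHD library. Between the Tfh libraries only 9 and 0 of the 100 were absent, so carry-over there stays open. Rearrangements that form often would also be found in the Tfh libraries, which held at most 0.0106 times the TRB reads that other cGVHD libraries held. This argues against frequent formation as the source of most shared reads. It cannot exclude independent formation within cGVHD mice, since the Tfh cells came from other mice given no donor Thy1.2+ cells. Of the 40 TRB clonotypes in all 5 cGVHD libraries, 3 were seen in a Tfh library, a higher share than the 1.08 to 1.88% of all TRB clonotypes of a cGVHD library. Frequent formation thus stays open for some of the 40. The data are consistent with descent from common expanded clones, as a hypothesis, since animals could not be traced and the route between blood and tissue was not measured. Whether the clones came from 1 animal or a pool stays open.

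TRBV26 was lower in the Tfh libraries, with disease, the donor cells given, tissue and cell type not varied alone. BALB/c superantigens that remove TRBV26 cells are the biological explanation considered. Of the other 4 list members, 2 (TRBV16 and TRBV12-2) had a lower clonotype share in both Tfh libraries than in each cGVHD library, TRBV15 did except against blood (1.84% against 2.02% and 2.20%), and TRBV12-1 went the other way, which argues against removal of the whole list. Removal of part of it stays open, since TRBV16, TRBV15 and TRBV12-2 passed as higher in cGVHD libraries by clonotypes and the list without TRBV26 took 11.9 to 17.8% of clonotypes there against 10.8% and 11.4% in Tfh libraries, although by reads it took 8.67% (cGVHD median) against 8.24% (Tfh mean). TRBV26 was also more frequent among out-of-frame clonotypes pooled over cGVHD libraries, 13 of 485 against 10 of 1559 (Fisher's exact p = 0.000681, which ignores the spread between libraries of 1.06 to 5.22% against 0.309% and 1.03%). With at least 20 reads the counts were 11 of 242 and 3 of 211 (Fisher's exact p = 0.0616). Removal from Tfh cells would put their in-frame share below their out-of-frame share. Pooled over Tfh libraries these shares were close (0.671% in frame, 0.641% out of frame). Single Tfh libraries went opposite ways (0.701% against 0.309%, and 0.546% against 1.03%). In cGVHD libraries the pooled in-frame share was higher (11.4% against 2.68%). With so few out-of-frame clonotypes, removal after rearrangement and another cause cannot be told apart. Other sequences of 80 or more nucleotides took more of the Tfh reads (0.0553% and 0.0919%) than of the cGVHD reads (0.00275 to 0.00848%) but a lower or similar part of the Tfh clonotypes (0.345% and 0.538% against 0.389 to 1.43%), and with as few as 11 reads in a library, loss of long sequences from the Tfh libraries and another cause cannot be told apart.

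TRA clonotypes of cGVHD libraries were found in the Tfh libraries far more than TRB clonotypes were. Carry-over is argued against, since it would act on both chains alike and the TRB share was at most 0.104 times the TRA share. Rearrangements that form often because they need few inserted nucleotides fit: in 5 of 5 cGVHD libraries the TRA clonotypes found in a Tfh library had a lower median of inserted nucleotides (0 against 1 or 2). No explanation by disease, donor cells given, tissue or cell type was tested, and whether these cells share a specificity stays open.

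TRBV30 and TRAV7-6 stood out because CD69+ and CD69- cells differed by reads in opposite directions in liver and lung, a difference between tissues that was not tested. By reads, TRBV30 was at least 1700-fold lower in CD69+ cells of liver, a bound that counts reads and not cells. It was 9.54-fold higher in CD69+ cells of lung, where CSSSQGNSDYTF made up 97.3% of its reads. By distinct clonotypes its share was lower in CD69+ cells of both tissues (0 against 0.452% and 0.130% against 0.613%). These shares rest on few clonotypes, 4 in liver CD69- and 2 in lung CD69+ cells, and show no clear direction. TRAV7-6 was 2.30-fold higher in CD69+ cells of liver and 2.15-fold lower in CD69+ cells of lung, and by distinct clonotypes it was slightly lower in both (1.69% against 1.78% and 1.69% against 2.06%).

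Reads out of frame or with a stop, which the comparisons of the main results left out, had a higher share in all 4 Trh libraries than in both Tfh libraries (4.07% and 4.26% for TRB, 10.5% and 10.4% for TRA), while blood Tph cells had a lower one (3.05% and 6.33%). They made up 4.87% (liver CD69+), 4.73% (liver CD69-), 4.80% (lung CD69+) and 12.1% (lung CD69-) of TRB reads and 12.9%, 11.2%, 12.5% and 15.8% of TRA reads.

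Clonotypes of 1 read, left out of the main results by the read minimum, were found at 100 or more reads in another library of the same condition at a higher share in cGVHD cells than in Tfh cells (0.180% and 0.668% for TRB, 0.384% and 0.713% for TRA). The comparison is uneven, since each cGVHD library had 4 other libraries to match and each Tfh library 1, and the Tfh libraries held 5549 and 4189 such TRB clonotypes against 122 to 220 in cGVHD libraries. Against a single other library the cGVHD shares were 0.781 to 23.0% for TRB and 0.893 to 21.2% for TRA. Against all 4 others the TRB shares were 10.6% in blood, 29.5% in liver CD69+, 8.59% in liver CD69-, 8.18% in lung CD69+ and 17.8% in lung CD69- cells, and for TRA they were 13.8%, 20.3%, 13.4%, 10.4% and 37.4%.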

How the results depend on the processing

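Of the values that answer a comparison, 123 were kept and 73 moved, and of the others 629 were kept, 342 moved and 15 lost their call with the direction unchanged. No called value reversed, but several differences that were not called by reads did. The TRA CDR3 length difference of 0.0136 residues was -0.0497 without Tfh library 2. By distinct clonotypes, the iNKT V beta list went from 21.2% (cGVHD median) against 23.9% (Tfh mean) to 21.1% against 20.3%. TRBV15 went from 1.25% against 1.62% to 3.07% against 2.11%. Alternatives without TRBV26 (by reads or clonotypes), without clonotypes found in a Tfh library, without the leading clonotype and without single Trh libraries in their mean were chosen after seeing the data. The cause of a shift was not tested unless the alternative itself removed reads, clonotypes or libraries. Matching by amino acid sequence gave blood Tph reads in Trh clonotypes of 59.1% (TRB) and 57.04% (TRA), in Tfh clonotypes of 9.73% and 53.7%, a TRB Morisita-Horn index of the Tfh pair of 0.256, a TRA share of the 10 most abundant clonotypes of 26.1% (cGVHD median) and a TRA clonotype ratio of Tfh mean over cGVHD median of 33.5. Matching by nucleotide sequence alone gave 0.859% (TRB) and 25.4% (TRA) of blood reads in Tfh clonotypes and 52.8% of TRA reads in Trh clonotypes. Without a read minimum, blood reads in Trh clonotypes were 65.8% and 59.0%, in Tfh clonotypes 0.804% and 12.1%, and the TRA ratio 33.8. With 10 reads as minimum, they were 57.2% and 51.5%, the TRA share in Tfh clonotypes 5.01%, the clonotype ratios 9.91 (TRB) and 22.8 (TRA) and the TRB share of the 10 most abundant in Tfh cells 9.67%. With all clonotypes listed, blood reads in Trh clonotypes were 58.1% and 51.6%, in Tfh clonotypes 0.517% and 10.04%, the 10 most abundant TRA clonotypes took 20.3% (cGVHD median) and 6.34% (Tfh mean), and the TRB indices were 0.709 (liver pair), 0.314 (lung pair) and 0.272 (Tfh pair). With the 200 most abundant clonotypes, blood reads were 44.9% and 41.9% in Trh and 0.157% and 2.59% in Tfh clonotypes, and the TRB indices 0.699, 0.345, 0.203 and 0.151 (mean of blood with Trh). With the rarer side at 1% or more, blood reads were 55.6% (TRB) and 50.5% (TRA) in Trh clonotypes and 5.81% (TRA) in Tfh clonotypes. Without clonotypes of either Tfh library the TRA share in Trh clonotypes was 51.2%. Without the leading clonotype, blood reads in Trh clonotypes were 58.0% and 52.3%, and the TRB indices 0.312 (liver pair), 0.284 (lung pair) and 0.173 (mean of blood with Trh). With single Tfh libraries left out, blood reads in Tfh clonotypes ranged from 0.149 to 0.338% (TRB) and 6.57 to 8.78% (TRA). The superantigen list took 22.7% (cGVHD median) and 11.7% (Tfh mean) by clonotypes, 14.6% (cGVHD) without the 5 most abundant clonotypes 8.67% (cGVHD) without TRBV26, and 13.9% (cGVHD) and 11.1% (Tfh) by clonotypes without TRBV26. Between cGVHD and Tfh libraries, TRB genes called were 4 with DESeq2's Wald test, 15 by clonotypes and 0 to 3 with single libraries left out, and TRA genes called were 2 with the Wald test, 2 with no filter and 8 by clonotypes. Where 1 Tfh library was left out, the remaining one was assumed to vary like the cGVHD libraries. For CD69 status, TRA genes called were 1 with DESeq2 size factors, 0 with the Wald test, 0 by clonotypes and 0 without the tissue term. The TRB CDR3 length difference was 1.85 residues by clonotypes and 0.171 without TRBV26. Leaving out single libraries was not run for CD69 status, since no residual degrees of freedom would remain, and TRAV2 had no value by clonotypes because it fell below the filter. Depth limits what an absence means: 0 reads allow shares up to 0.00116% of TRB reads in a cGVHD library. No paired analysis was possible because the labels do not say which animals gave which library and the groups share fewer than 2 replicate numbers. The tissue block of the CD69 test matched libraries by tissue, not by animal.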

Other observations

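The No GVHD Tfh cells had their own leading receptors, and none of the leading TRB clonotypes was found in a cGVHD library. In Tfh library 1 the TRBV16 clonotype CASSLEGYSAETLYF took 1.502% of TRB reads, the TRBV5 clonotype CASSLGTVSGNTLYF 1.12% and the TRBV29 clonotype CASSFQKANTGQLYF 0.885%. In Tfh library 2 the TRBV29 clonotypes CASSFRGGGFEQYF and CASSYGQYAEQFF took 2.29% and 1.43% and the TRBV13-1 clonotype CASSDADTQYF 1.11%. Each of these 6 was found in both Tfh libraries, for example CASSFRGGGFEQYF with 0.319% in library 1. Among TRA chains, the leaders were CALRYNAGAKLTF (1.39%), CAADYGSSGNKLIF (0.992%) and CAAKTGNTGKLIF (0.936%) in library 1 and CAIRSGSGGKLTL (1.31%) and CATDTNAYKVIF (0.921%) in library 2, these 5 with 0 reads in the cGVHD libraries. The third of library 2, the TRAV4-4 clonotype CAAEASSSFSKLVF (0.801%), took 1.54 to 4.89% in the cGVHD libraries.

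As a hypothesis formed here, with a test chosen after the result was seen, the leading TRB clonotype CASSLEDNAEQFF and the leading TRA clonotype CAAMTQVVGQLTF are the 2 chains of 1 expanded cell clone. The ratio of their shares ran from 0.827 to 1.66 over the 5 cGVHD libraries, and among the 15 TRA clonotypes found in all 5 the TRAV14-3 clonotype ranked 1 for the steadiness of that ratio (SD of the log2 ratio 0.427, against 1.46 for the next). Both were picked because they led the same 3 libraries, so this rank restates what prompted the hypothesis and is no independent evidence for it. Pairing of the chains within a cell was not measured, and the hypothesis stays open.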
